A study of Mus musculus with 24 samples.

How the data were processed

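The series holds 24 arrays of total RNA from MLO-Y4 cells, 3 for each of 8 groups that cross an antibody (irrelevant rabbit IgG or Cx43(E2)) with an environment (incubator, or the 1g, 2g or ug position of the platform). Per the labels' protocols, antibody was added at a 1:50 dilution (28 µg/ml for Cx43(E2)) for 30 min at 37 °C in 5% CO2 before the groups were parted, RNA was extracted with Trizol, and biotin-labelled cRNA was made after the Affymetrix protocol. The time on the platform is not given. The deposited values are log2 intensities, judged from the values themselves, which run from 2.36 to 14.06 with array medians between 6.48 and 6.65 and interquartile ranges between 3.69 and 3.92. Per the submitters' processing notes MAS5 was used, with no role or version. How the authors scaled the arrays to one another is not stated, and the arrays do not share 1 set of quantiles. Groups were read from sample titles and source names. Replicates were separate arrays: differences between replicates had an SD of 0.122 to 0.354, with at most 6 identical values. Arrays give no counts, so their number limits the precision.

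The table has 35556 rows (probe sets). The array's probe table gave a gene symbol for 23410 of them, exactly 1 symbol for 21789 and several for 1621, and did not list 12146. Of the rows with 1 symbol, 21698 matched the RefSeq table by gene number and 91 did not. No coordinates are given, since no build is stated. Rows were kept if they reached the 40th percentile of their array on at least 3 of the 24 arrays, which left 22641 rows and 15786 with 1 symbol. The brightest row of each gene was used, which gave 14489 genes. Rows with no symbol or several were left out of the comparisons and tested apart.

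Genes were tested with limma 3.58.1 in R 4.3.3: 8 group means fitted over all arrays without a block, 15 contrasts, moderated variances with a trend, two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. There were 16 residual degrees of freedom and a prior of 4.08 (12 and 8.29 with the block within arm). The 28 gene lists were written from textbook knowledge and tested with camera (limma) at its preset correlation, adjusted over the lists of a comparison. No list called in the 15 comparisons of the design held with an estimated correlation when no block was used. Fits, contrasts, lists and the alternatives in the design were fixed before the data were examined. Genes were named by rule: for platform positions against the incubator in the IgG arm and for E2 against IgG, the 10 largest rises and falls among called genes whose arrays do not overlap, 5 of each elsewhere, Gja1 always, and up to 4 members with the smallest p of each list described. The added comparisons name 10 of each direction. Single members of lists that are not described (among them Rrm2, Grem1, Lox, Gja3, Atg3, Itga1 and Fth1), the 7 genes called with the block, Gem and Cirbp were chosen after their values were seen.

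The titles give each group replicate numbers 1 to 3. Whether the numbers pair the arrays was checked from correlations of deviations from group means across genes, which are not independent replicates. Within an arm, all 36 pairs with the same number lay above 0.1 (0.195 to 0.812, median 0.511), and 20 of 24 arrays correlated best with an array of their own number. Of the 72 pairs with different numbers, 23 also lay above 0.1 (highest 0.548, median -0.452). These joined numbers 1 and 2, which correlated at 0.150 to 0.548 (median 0.332) in the IgG arm and 0.0230 to 0.482 (median 0.314) in the E2 arm, so the pairing rests mostly on number 3. Between arms the 48 pairs with the same number lay between -0.748 and -0.0141. The numbers were therefore taken to pair arrays within an arm, from the values and not from a label, and the block has 6 levels of arm and number. It cannot be fitted to a difference between arms in 1 environment. Comparisons added after the data were seen used this block: the mean of the 3 positions against the incubator in each arm, in both and between them, and ug against C, 1g and 2g in both arms.

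Alternatives were the number as a block over all arrays, the block within arm, quantile normalization, no filter on dim rows, the mean of a gene's rows, no variance trend, only the arrays compared, and leaving out each replicate. Added after the data were seen were the set as a random block (consensus correlation 0.355), fry on the blocked fit (genes scaled beforehand by their posterior SD, a change made after its results were seen because fry's own scaling varied with how the design was written), fits without the 2g and ug arrays of set IgG 2, and E2 against IgG on the means over the 4 environments of each set. Chance correlation between comparisons with a shared control came from 200 simulations. The code was tested on simulated data with 200 of 14489 genes altered. For 1g against C in the IgG arm without a block, 4%, 64%, 88% and 100% of genes altered by 0.25, 0.5, 1 and 2 (log2) were recovered, with 0 unaltered genes called, and with the block 34%, 86%, 98% and 100%, with 6. For E2 against IgG in the incubator the shares were 16%, 50%, 94% and 98%, and 88 unaltered genes were called. The simulated arrays kept the real mean of each set, and sets lie within arms. Genes counted as unaltered thus carried the real difference between the arms. Neither these 88 calls nor the shares recovered therefore measure the error of the E2 comparison.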

Results

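Gene expression was measured on 24 arrays of RNA from MLO-Y4 cells, a mouse cell line with osteocyte features, with 3 arrays in each of 8 groups. Cells received either an irrelevant rabbit IgG (the IgG arm) or Cx43(E2), an antibody that blocks hemichannels made of connexin 43 (the E2 arm). They then stayed at 1 of 3 positions on a platform in a high magneto-gravitational environment, labelled 1g, 2g and μg (ug here), or in an incubator (C). The 8 groups pair each arm with each environment. The 4 arrays that share an arm and a replicate number are called a set here, so that IgG 2 is the set of number 2 in the IgG arm. Array medians lay between 6.48 and 6.65 on the log2 scale, and 14489 genes were tested. Brackets after a gene give its probe set number where it first appears, then its log2 change ± standard error. Adjusted p-values come from limma for genes and from its camera test for 28 gene lists. They measure only the spread between these arrays, since no label says that the replicates were separate cultures. The number of arrays limits the precision.

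Gja1 (10363173, the gene of connexin 43, the antibody's target) was bright on every array. Its group means ran from 11.64 ± 0.23 to 11.74 ± 0.22 on the log2 scale (SD, n = 3). Its log2 change lay between -0.08 and 0.11 in the 15 comparisons of the design (SE 0.18, or 0.26 for differences between antibody effects), and no adjusted p fell below 0.851. The antibody binds protein, so the RNA level of Gja1 checks no label. Arrays of 1 set correlated across genes in their deviations from the group means (r between 0.195 and 0.812), which is why sets were used as a block. Sets numbered 1 and 2 of an arm were less distinct: r between them was 0.150 to 0.548 in the IgG arm and 0.0230 to 0.482 in the E2 arm. The first principal component held 44.6% of the variance and the second 17.9%. Sets IgG 1, IgG 2 and E2 3 lay below 0 on the first component, and sets IgG 3, E2 1 and E2 2 lay above 0, with no array out of place. Gja1 followed that division: it lay between 11.37 and 11.59 on the arrays of the former sets and at 11.75 or above on those of the latter.

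**Figure D1:**
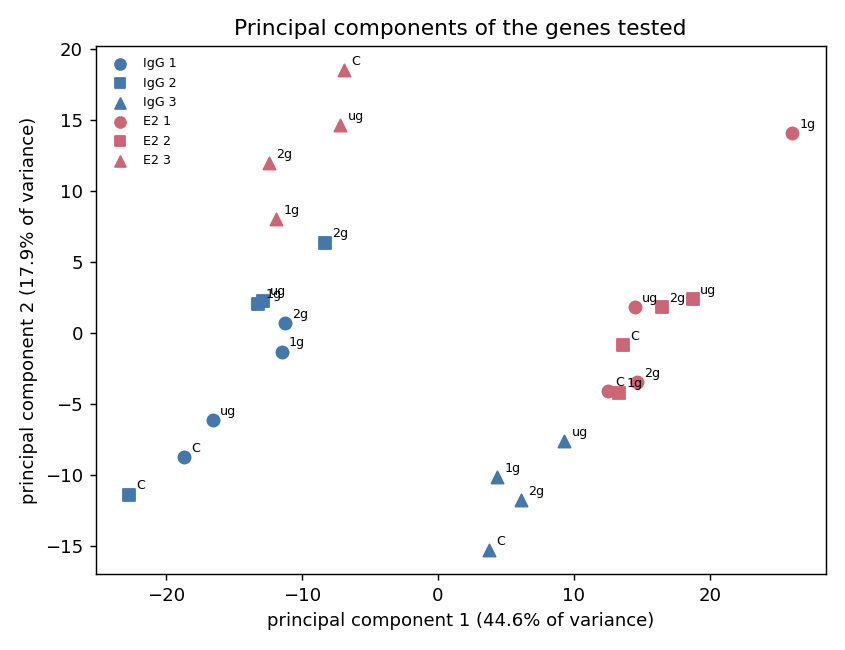
Principal components 1 and 2 of the 14489 genes tested (axes in component scores, with the percent of variance), with 1 point per array, colour for the antibody arm, marker shape for the replicate number and text for the environment. All 12 arrays of sets IgG 1, IgG 2 and E2 3 lie left of 0, and all 12 of sets IgG 3, E2 1 and E2 2 lie right of 0.

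The first question was how each platform position differed from the incubator in cells given the irrelevant IgG. At 1g, the targets of NRF2, the transcription factor of the antioxidant response, fell as a list (16 of 19 lower, median -0.08, camera adjusted p = 0.0438, adjusted p = 0.608 with an estimated correlation, adjusted p = 0.281 after quantile normalization). The smallest p-values belonged to Txn1 (10513195, -0.08 ± 0.03), Gsr (10571274, -0.10 ± 0.07), Mt2 (10574023, -0.07 ± 0.05) and Txnrd1 (10365260, -0.20 ± 0.16), none of them past its own test. At 2g the unfolded protein response, the set of chaperones and regulators that cells raise when proteins misfold in the endoplasmic reticulum, rose as a list (17 of 20 higher, median 0.07, camera adjusted p = 0.0256, adjusted p = 0.672 with an estimated correlation). It included Herpud1 (10574087, 0.43 ± 0.16), Hyou1 (10584712, 0.20 ± 0.07), Creld2 (10426098, 0.16 ± 0.07) and Sdf2l1 (10438098, 0.30 ± 0.13), none of them called over all genes. At 2g the genes of oxidative phosphorylation fell as a list (18 of 23 lower, median -0.05, camera adjusted p = 0.0256, adjusted p = 0.758 with an estimated correlation, adjusted p = 0.166 after quantile normalization). Markers of endothelial cells rose as a list at 2g (9 of 9 higher, median 0.12, camera adjusted p = 0.0286, adjusted p = 0.672 with an estimated correlation, adjusted p = 0.175 after quantile normalization). The median level of those 9 genes was 6.39, against 8.41 for all genes tested, and that of the oxidative phosphorylation list was 10.9. All genes below the median level (dimmer genes) had a median change of 0.04 at 1g, 0.06 at 2g and 0.04 at ug, and those above it (brighter genes) of -0.02, -0.03 and -0.03. The falls of the 2 bright lists (11.9 for targets of NRF2) and the rise of the dim list went the way of this shift by level. The unfolded protein response, with a median level of 11.1, went against it. At ug no list passed. Adjusted over the list alone, Hspb1, a small heat shock protein, was higher at 1g (10408928, 0.36 ± 0.09, n = 3 per group) and at ug (0.31 ± 0.09), and Rrm2, a subunit of ribonucleotide reductase, was lower at 2g (10394978, -0.14 ± 0.04) and at ug (-0.14 ± 0.04).

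Over all genes, limma called 0 genes at 1g, 0 at 2g and 0 at ug, with 886, 1272 and 748 genes at an unadjusted p below 0.05. If no gene changes, chance alone gives a share of 0.05 of the 14489 genes, which the 748 at ug barely exceeds. Each such count below is to be set against the same share. With the replicate block within arm, limma called 7 genes at 1g. Of these 3 rose, Banp (10576073, 0.51 ± 0.07), Hspb1 (0.36 ± 0.06) and Serpinh1 (10565794, 0.32 ± 0.05), and 4 fell, Rnf125 (10454198, -0.49 ± 0.08), Nipal1 (10522368, -0.53 ± 0.10), Olfr810 (10373642, -0.62 ± 0.11) and Map3k20 (10472893, -0.26 ± 0.05), with adjusted p between 0.0127 and 0.0492 and standard errors from that fit. Serpinh1 is a collagen chaperone. At 2g the same block made camera call 5 lists, adding the targets of NRF2 (adjusted p = 0.00469, and 0.417 with an estimated correlation) and chondrocyte markers (adjusted p = 0.0421, and 0.813 with an estimated correlation). The 3 platform and 3 incubator arrays did not overlap for 15.9% of genes at 1g, 19.3% at 2g and 13.0% at ug, where chance gives 10% if all 6 arrays are exchangeable. Arrays of 1 set resembled each other, so that share is not exact here. Against 1g in the IgG arm, 5.63% of genes did not overlap at ug and 7.96% at 2g (10% by chance). In the E2 arm the shares against the incubator were 5.51% at 1g, 4.79% at 2g and 8.07% at ug, also against 10%.

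The mean of the 3 positions against the incubator in the IgG arm was compared after the data were seen, in the fit with the block within arm. Here 17 genes rose and 85 fell (limma, adjusted p below 0.05), and all 102 moved in the same direction in 3 of 3 sets. Being called in the blocked fit favours such agreement, so it is no separate support. Among the rises were the heat shock genes Hspa1a (10450369, 0.42 ± 0.09) and Hspb1 (0.31 ± 0.05), along with Banp (0.46 ± 0.06), Tmem204 (10448836, 0.36 ± 0.07), Itpr3os (10449312, 0.35 ± 0.07) and Hnf4aos (10489372, 0.35 ± 0.07). Others were Gm10069 (10542104, 0.35 ± 0.08), Efna2 (10364722, 0.34 ± 0.06), Vpreb2 (10434128, 0.30 ± 0.07) and Bik (10425801, 0.29 ± 0.06). Bik encodes a protein that promotes apoptosis. The largest falls were Nipal1 (-0.47 ± 0.08), Olfr810 (-0.47 ± 0.09), Ankrd49 (10590968, -0.46 ± 0.10), Dennd4a (10586240, -0.41 ± 0.08) and Nkapd1 (10593361, -0.39 ± 0.09). Next came Trdmt1 (10480224, -0.39 ± 0.08), Phf20l1 (10424467, -0.39 ± 0.08), Mzt1 (10457331, -0.39 ± 0.09), Casp4 (10582997, -0.38 ± 0.09) and Alg11 (10570764, -0.38 ± 0.08). Adjusted p for these 20 genes lay between 0.00327 and 0.0422. Among the rises, Itpr3os, Hnf4aos, Vpreb2, Bik and Tmem204 were dim. Their mean levels were 6.16, 6.32, 6.38, 6.39 and 6.66, against a median of 8.41 for all genes tested. The targets of NRF2 fell as a list (16 of 19 lower, median -0.05, camera adjusted p = 0.00385, adjusted p = 0.299 with an estimated correlation). It had 5 members lower when adjusted over the list alone. Of these, thioredoxin reductase 1, Txnrd1 (-0.19 ± 0.04), also passed over all genes (adjusted p = 0.0174), while Nqo1 (10581538, -0.10 ± 0.03), Slc7a11 (10498024, -0.31 ± 0.08) and Gclm (10495763, -0.09 ± 0.03) did not. The unfolded protein response rose as a list (15 of 20 higher, median 0.06, camera adjusted p = 0.0157, adjusted p = 0.918 with an estimated correlation). Its 4 members higher when adjusted over the list alone were Sdf2l1 (0.29 ± 0.06), Herpud1 (0.36 ± 0.10), Hyou1 (0.15 ± 0.04) and Creld2 (0.13 ± 0.04). Sdf2l1 alone of these 4 passed over all genes (adjusted p = 0.0391). Dimmer genes had a median change of 0.05 and brighter genes of -0.03. Without the block limma called 0 genes. Leaving out set IgG 1, 2 or 3 left 0, 0 and 2 genes, and leaving out the 2g and ug arrays of set IgG 2 left 4. The count was 67 with no filter on dim probe sets, 47 with no trend in the variance and 20 with the set as a random block. After quantile normalization 81 genes were called, 47 of them among the 102, with 49 rises and 32 falls, so the share of rises moved from 16.7% to 60.5%.

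**Figure D2:**
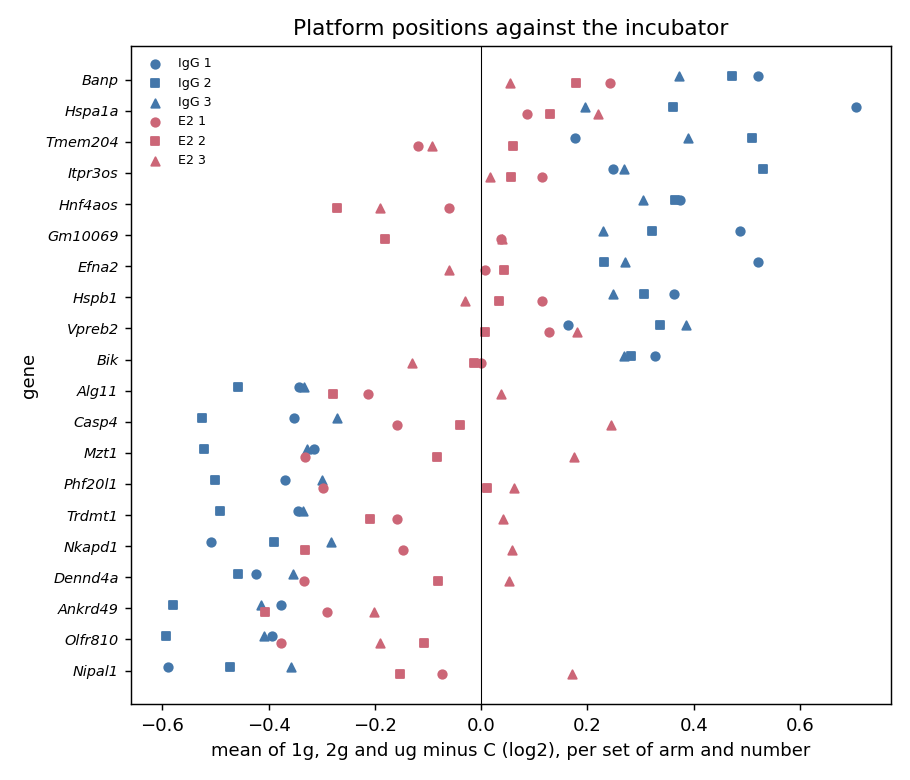
Mean of the 1g, 2g and ug arrays minus the incubator array (x axis, log2) of each set, for the 10 largest rises and 10 largest falls in the IgG arm (y axis, genes), with colour for the arm and marker shape for the replicate number. In the IgG arm all 3 sets lie on 1 side of 0 for each of the 20 genes, which were chosen for their change in that arm.

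Within the IgG arm, the ug and 2g positions were compared with 1g on the platform. No test separated gravity from other differences between positions, such as the magnetic field. At ug the immediate early genes, which cells switch on within minutes of a stimulus, rose as a list (22 of 24 higher, median 0.17, camera adjusted p = 3.06e-06, adjusted p = 0.704 with an estimated correlation). The members with the smallest p were Atf3 (10361091, 0.56 ± 0.31), Egr1 (10454782, 0.57 ± 0.33), Klf6 (10403352, 0.21 ± 0.13) and Fosb (10560481, 0.57 ± 0.36), and none passed alone. Set IgG 3 carried most of this rise: ug minus 1g was 0.34, -0.26 and 1.63 for Fosb and 0.39, -0.19 and 1.49 for Atf3 in sets IgG 1, 2 and 3. The mean of the list's deviations from each gene's own mean was -0.08 at 1g and -0.05 at ug in set IgG 1, -0.24 and -0.28 in IgG 2, and -0.19 and 0.47 in IgG 3. At 2g the genes of the extracellular matrix rose as a list (22 of 27 higher, median 0.06, camera adjusted p = 0.0143, adjusted p = 0.588 with an estimated correlation). They included Fn1 (10355403, 0.08 ± 0.04), Mmp2 (10573924, 0.08 ± 0.05), Plod2 (10587829, 0.14 ± 0.08) and Timp2 (10393559, 0.05 ± 0.04). Chondrocyte markers, with a median level of 7.52, also rose at 2g (8 of 8 higher, median 0.11, camera adjusted p = 0.0124, adjusted p = 0.588 with an estimated correlation). Without the 2g and ug arrays of set IgG 2 the adjusted p was 0.0612. Genes of oxidative phosphorylation fell at 2g (20 of 23 lower, median -0.04, camera adjusted p = 0.00656, adjusted p = 0.588 with an estimated correlation). No member of these 4 results passed when adjusted over the list alone. Limma called 0 genes at ug and 0 at 2g, with 162 and 259 at an unadjusted p below 0.05. Both counts lie below the share of 0.05 that chance alone gives. That fit has no block, so differences between sets count as spread, and the block gave 494 and 725. With the block, camera called 8 lists instead of 1 at ug and 10 instead of 3 at 2g. The 7 added at ug were higher there: chondrocyte markers and the lists of cytokines, heat shock proteins, targets of NRF2, iron handling, targets of p53 and cholesterol synthesis (adjusted p between 0.00442 and 0.0496, and between 0.407 and 0.698 with an estimated correlation). Of the 7 added at 2g, the YAP and SRF targets with actin genes were lower, and osteocyte markers, osteoblast markers, cytokines, immediate early genes, the unfolded protein response and the interferon response were higher (adjusted p between 0.00557 and 0.0384, and between 0.527 and 0.618 with an estimated correlation).

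In cells given the hemichannel-blocking antibody, the same positions were compared with the incubator. At ug the immediate early genes rose together (24 of 24 higher, median 0.41, camera adjusted p = 5.72e-22, adjusted p = 0.139 with an estimated correlation). Adjusted over the list alone, 6 of them were higher, among them the transcription factor genes Atf3 (1.39 ± 0.31), Fosb (1.39 ± 0.36) and Fos (10397346, 1.21 ± 0.34) and Zfp36 (10561453, 0.59 ± 0.20), which encodes a protein that promotes decay of cytokine messengers. Cytokine genes also rose as a list (14 of 19 higher, median 0.09, camera adjusted p = 2.19e-04, adjusted p = 0.184 with an estimated correlation). Of these Tnf (10450501, 0.86 ± 0.23) passed when adjusted over the list alone. Ribosomal proteins rose as a list (16 of 16 higher, median 0.07, camera adjusted p = 7.55e-10, adjusted p = 0.139 with an estimated correlation). Their changes were small, as in Rpl13 (10531340, 0.17 ± 0.05), Rps19 (10551021, 0.32 ± 0.11) and Rpl27 (10381402, 0.11 ± 0.05). Oxidative phosphorylation rose as a list (19 of 23 higher, median 0.05, camera adjusted p = 1.44e-06, adjusted p = 0.193 with an estimated correlation). Its members included Ndufa1 (10604100, 0.34 ± 0.13), Ppargc1a (10529979, 0.53 ± 0.29) and Ndufa4 (10543134, 0.14 ± 0.08). Heat shock proteins rose (12 of 16 higher, median 0.07, camera adjusted p = 1.54e-04, adjusted p = 0.217 with an estimated correlation). Their members included Hspb8 (10533050, 0.19 ± 0.06), Hspa1a (0.38 ± 0.17), Ahsa1 (10397518, 0.15 ± 0.07) and Bag3 (10557992, 0.21 ± 0.12). Another 5 lists rose at ug. The unfolded protein response was higher (15 of 20 higher, median 0.03, camera adjusted p = 0.00449, adjusted p = 0.217 with an estimated correlation, adjusted p = 0.163 after quantile normalization). Targets of NRF2 rose (14 of 19 higher, median 0.05, camera adjusted p = 0.011, adjusted p = 0.184 with an estimated correlation, adjusted p = 0.315 after quantile normalization). Autophagy and lysosome genes rose (13 of 19 higher, median 0.05, camera adjusted p = 0.0186, adjusted p = 0.526 with an estimated correlation, adjusted p = 0.232 after quantile normalization). So did targets of p53 (10 of 16 higher, median 0.05, camera adjusted p = 0.0197, adjusted p = 0.476 with an estimated correlation, adjusted p = 0.0536 after quantile normalization). Nuclear and small RNA genes rose (5 of 6 higher, median 0.07, camera adjusted p = 0.0197, adjusted p = 0.142 with an estimated correlation, adjusted p = 0.2 after quantile normalization).

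At 2g in the E2 arm the unfolded protein response rose (17 of 20 higher, median 0.09, camera adjusted p = 2.49e-06, adjusted p = 0.136 with an estimated correlation). Its smallest p-values belonged to the disulfide isomerase genes Pdia3 (10475335, 0.17 ± 0.07) and Pdia6 (10394735, 0.11 ± 0.05). Oxidative phosphorylation also rose (18 of 23 higher, median 0.03, camera adjusted p = 1.84e-05, adjusted p = 0.404 with an estimated correlation, adjusted p = 0.139 after quantile normalization). Its member Ndufa9 (10548057, 0.23 ± 0.06) passed when adjusted over the list alone. Ribosomal proteins rose at 2g (14 of 16 higher, median 0.04, camera adjusted p = 4.06e-05, adjusted p = 0.404 with an estimated correlation, adjusted p = 0.46 after quantile normalization). Heat shock proteins rose there (14 of 16 higher, median 0.04, camera adjusted p = 0.00166, adjusted p = 0.532 with an estimated correlation, adjusted p = 0.139 after quantile normalization). Autophagy and lysosome genes did so too (15 of 19 higher, median 0.04, camera adjusted p = 0.043, adjusted p = 0.675 with an estimated correlation, adjusted p = 0.436 after quantile normalization). Nuclear and small RNA genes rose at 2g as well (4 of 6 higher, median 0.06, camera adjusted p = 0.0414, adjusted p = 0.221 with an estimated correlation, adjusted p = 0.436 after quantile normalization). At 1g, 3 lists rose. The unfolded protein response was 1 of them (14 of 20 higher, median 0.06, camera adjusted p = 0.00316, adjusted p = 0.679 with an estimated correlation, adjusted p = 0.878 after quantile normalization). Oxidative phosphorylation was another (16 of 23 higher, median 0.04, camera adjusted p = 0.00316, adjusted p = 0.679 with an estimated correlation, adjusted p = 0.878 after quantile normalization). Ribosomal proteins also rose (13 of 16 higher, median 0.03, camera adjusted p = 0.00316, adjusted p = 0.679 with an estimated correlation, adjusted p = 0.878 after quantile normalization). Limma called 0 genes at 1g, 0 at 2g and 0 at ug (n = 3 per group), with 453, 285 and 611 at an unadjusted p below 0.05. Without E2 replicate 1 at ug, 1 gene was called there. Dimmer genes had median changes of -0.05, -0.03 and -0.03 at the 3 positions, and brighter genes of 0.01, -6.04e-04 and -0.02. The unfolded protein response, oxidative phosphorylation and ribosomal proteins were bright, with median levels of 11.1, 10.9 and 12.2. At 1g, where brighter genes rose and dimmer genes fell, the rises of these lists went the way of this shift by level. At 2g and ug the median of brighter genes lay below 0 while these lists rose. Ribosomal proteins and oxidative phosphorylation still passed at ug after quantile normalization, whereas none of these lists did at 1g. With the block, camera added lists, all of them higher. Cholesterol synthesis and autophagy were added at 1g (adjusted p = 0.00425 and 0.0184), and the interferon response at 2g (adjusted p = 0.0468). Cholesterol synthesis and iron handling were added at ug (adjusted p = 0.00153 and 0.0469). The nuclear and small RNA genes were lost at 2g (adjusted p = 0.0615). With an estimated correlation the added lists had adjusted p between 0.29 and 0.778.

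Ug against the incubator over both arms was compared after the data were seen, with the block. Here 35 genes rose and 56 fell (limma), and 82 of the 91 moved in the same direction in 6 of 6 sets, which being called in the blocked fit favours. Among those 82, the largest rises were the immediate early genes Fosb (1.05 ± 0.21), Atf3 (1.05 ± 0.20), Fos (0.93 ± 0.20) and Arc (10429491, 0.67 ± 0.13), together with A3galt2 (10508368, 0.88 ± 0.15), Rsrp1 (10509014, 0.63 ± 0.10), Mir99ahg (10436596, 0.56 ± 0.13), Gadd45b (10364950, 0.55 ± 0.10), Fbxo39 (10378078, 0.55 ± 0.11) and Trim69 (10475420, 0.52 ± 0.10). Gem, singled out after its values were seen, rose more than these (10503334, 2.38, adjusted p = 0.0272), but went the other way in set IgG 2. The largest fall among the 82 was that of Il1a (10487588, -0.71 ± 0.11), the gene of interleukin 1 alpha. Others that fell were the thioredoxin-binding protein gene Txnip (10494428, -0.37 ± 0.08), the receptor genes S1pr1 (10501586, -0.34 ± 0.08), Lpar6 (10416371, -0.34 ± 0.07) and Ackr2 (10590427, -0.37 ± 0.08), and Ankrd49 (-0.38 ± 0.09), Cdc42ep3 (10453049, -0.36 ± 0.06), Medag (10527649, -0.34 ± 0.06), Fam43a (10434932, -0.33 ± 0.06) and Naip2 (10411595, -0.33 ± 0.07). Adjusted p for these 20 genes lay between 0.0107 and 0.0489. Among the rises, A3galt2, Trim69, Fbxo39 and Mir99ahg were dim, with mean levels of 6.01, 6.03, 6.25 and 6.69, against a median of 8.41 for all genes tested. The immediate early genes rose as a list (22 of 24 higher, median 0.26, camera adjusted p = 1.48e-14, adjusted p = 0.373 with an estimated correlation). Adjusted over the list alone, 11 of them were higher, with Klf4 (0.34 ± 0.07) past the test over all genes as well (adjusted p = 0.0282). Over both arms they were higher at ug than at 1g (23 of 24 higher, median 0.25, camera adjusted p = 1.52e-18, adjusted p = 0.322 with an estimated correlation). They were also higher at ug than at 2g (22 of 24 higher, median 0.29, camera adjusted p = 8.03e-20, adjusted p = 0.339 with an estimated correlation). Camera called 6 other lists between ug and 1g (adjusted p between 3.93e-04 and 0.0163, and between 0.322 and 0.49 with an estimated correlation), of which YAP and SRF targets with actin genes were lower and cytokines, heat shock proteins, targets of NRF2 and p53, and ribosomal proteins were higher. It called 9 other lists between ug and 2g (adjusted p between 0.00802 and 0.0355, and between 0.481 and 0.682 with an estimated correlation). Hypoxia and glycolysis, the interferon response and the extracellular matrix were lower, and cytokines, targets of NRF2 and p53, cholesterol synthesis, oxidative phosphorylation and ribosomal proteins were higher. Of these 9, cytokines had an adjusted p of 0.0532 after quantile normalization. Without the 2g and ug arrays of set IgG 2, targets of p53 had 0.0694 and the extracellular matrix 0.0818. In set IgG 2 the immediate early genes were higher at 2g than at ug for 22 of 24 members: Fosb read 7.29 at ug and 8.22 at 2g, and Fos read 6.91 and 7.50. Heat shock proteins rose over both arms too (12 of 16 higher, median 0.07, camera adjusted p = 1.58e-04, adjusted p = 0.326 with an estimated correlation). So did the unfolded protein response (16 of 20 higher, median 0.02, camera adjusted p = 2.12e-04, adjusted p = 0.504 with an estimated correlation). Camera called 4 more lists, all higher: cholesterol synthesis, oxidative phosphorylation, ribosomal proteins and chondrocyte markers (adjusted p between 0.00482 and 0.0329, and between 0.504 and 0.604 with an estimated correlation). Without the 2g and ug arrays of set IgG 2, chondrocyte markers had an adjusted p of 0.0614. Without the block limma called 0 genes, and leaving out 1 set at a time gave 0 (IgG 1), 54 (IgG 2), 2 (IgG 3), 1 (E2 2) and 14 (E2 3). The count was 20 with no trend in the variance and 22 with the set as a random block. The balance of rises and falls turned around under several alternatives. After quantile normalization there were 36 rises and 28 falls, with 56 of these 64 genes among the 91. Without the 2g and ug arrays of set IgG 2 there were 62 rises and 32 falls, with 61 of these 94 genes among the 91. There were 14 rises and 8 falls with the random block, 37 and 17 without set IgG 2, 2 and 0 without set IgG 3, and 57 and 53 without set E2 1. Over both arms, 0 genes separated ug from 1g and 0 separated ug from 2g, with 1587 and 1143 at an unadjusted p below 0.05. These 2 counts were 65 and 56 without the 2g and ug arrays of set IgG 2, and 47 and 48 without the whole set. They were 22 and 2 without set E2 1, and 15 and 0 without set E2 3. Between ug and 1g, 1 gene was called with no filter on dim probe sets and 1 with the random block.

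**Figure D3:**
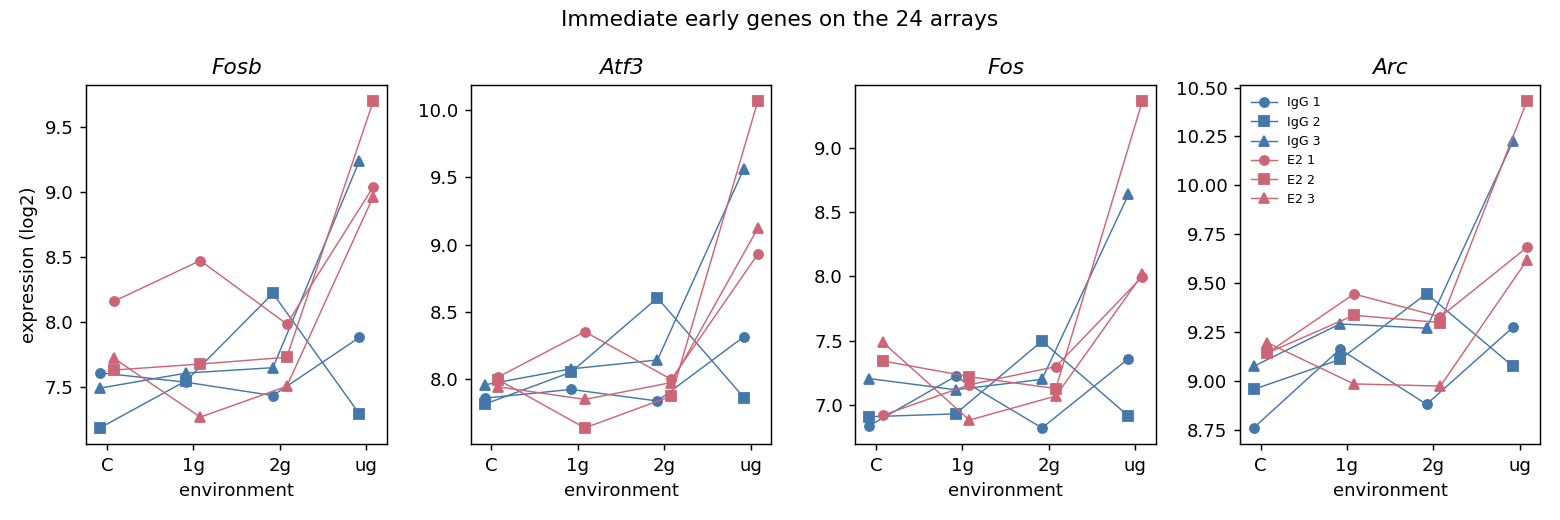
Expression (y axes, log2, not starting at 0) of Fosb, Atf3, Fos and Arc by environment (x axes) on the 24 arrays, with a line joining the 4 arrays of each set, colour for the arm and marker shape for the replicate number. In 5 of 6 sets the ug array is the highest for Fosb, Atf3 and Fos, and in set IgG 2 the 2g array is.

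The mean of the 3 positions against the incubator over both arms, also compared after the data were seen, gave 15 rises and 82 falls (limma with the block). Of the 97 genes, 81 moved in the same direction in 6 of 6 sets, which being called in the blocked fit favours. Rises included Rsrp1 (0.41 ± 0.08), Banp (0.31 ± 0.04), Hspa1a (0.28 ± 0.06), Ogt (10601235, 0.23 ± 0.05) and Serpinh1 (0.17 ± 0.03) and the small nucleolar and telomerase RNA genes Snord14e (10584580, 0.29 ± 0.05), Snora16a (10508719, 0.16 ± 0.04) and Terc (10500345, 0.20 ± 0.04), with Vpreb2 (0.20 ± 0.05) and Ube2ql1 (10410460, 0.18 ± 0.04). Falls included Il1a (-0.42 ± 0.09) and Stc1 (10416181, -0.29 ± 0.05), the genes of a cytokine and of a secreted glycoprotein, and 2610005L07Rik (10570639, -0.42 ± 0.09), Ankrd49 (-0.38 ± 0.07), Olfr810 (-0.35 ± 0.07), Rnf125 (-0.34 ± 0.04), Lpar6 (-0.30 ± 0.06), Slc25a36 (10479979, -0.30 ± 0.06), Vps37a (10571415, -0.28 ± 0.06) and Pcmtd1 (10344707, -0.28 ± 0.05). Adjusted p for these 20 genes lay between 0.00253 and 0.0486. Vpreb2 and Ube2ql1 were dim, with mean levels of 6.38 and 6.37. Grem1, an antagonist of bone morphogenetic proteins, fell (10485948, -0.12 ± 0.02, adjusted p = 0.00944), as did Lox, the collagen cross-linking enzyme (10458894, -0.11 ± 0.02, adjusted p = 0.0358). The unfolded protein response rose as a list over both arms (16 of 20 higher, median 0.06, camera adjusted p = 4.75e-07, adjusted p = 0.403 with an estimated correlation). Heat shock proteins rose likewise (12 of 16 higher, median 0.03, camera adjusted p = 0.00341, adjusted p = 0.403 with an estimated correlation). So did the immediate early genes (19 of 24 higher, median 0.06, camera adjusted p = 0.00654, adjusted p = 0.87 with an estimated correlation). In the E2 arm alone limma called 0 genes for the mean of the 3 positions, with 1004 at an unadjusted p below 0.05. There camera called 13 lists, all higher (adjusted p between 3.94e-08 and 0.0476, and between 0.103 and 0.553 with an estimated correlation). After quantile normalization 8 of the 13 were no longer called. Without the block the count over both arms was 0. It was 43 after quantile normalization (19 rises and 24 falls, 36 of the 43 among the 97), 59 with no filter on dim probe sets, 35 with no trend in the variance, 8 with the set as a random block and 13 without the 2g and ug arrays of set IgG 2. Leaving out a set gave 8 (IgG 1), 1 (IgG 2), 30 (IgG 3), 42 (E2 1) and 13 (E2 2).

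The effect of the hemichannel-blocking antibody itself was tested within each environment. In the incubator 232 genes were higher and 191 lower in the E2 arm than in the IgG arm (limma, n = 3 per arm). Among called genes whose arrays did not overlap, the 10 largest falls included the endosomal tethering gene Eea1 (10365933, -0.82 ± 0.22), the histone demethylase gene Kdm7a (10544148, -0.80 ± 0.19), the gene of the Rab escort protein Chm (10606513, -0.77 ± 0.20), the tRNA methyltransferase gene Alkbh8 (10582925, -0.72 ± 0.19) and the spindle gene Haus6 (10514201, -0.72 ± 0.19). The others were Zfp518a (10463121, -0.97 ± 0.24), Purb (10384150, -0.83 ± 0.22), Gpcpd1 (10487945, -0.74 ± 0.19), Olfr810 (-0.73 ± 0.17) and Zfp141 (10552314, -0.72 ± 0.17). The largest rises among them were Olfr767 (10373610, 0.87 ± 0.21), Rtbdn (10573472, 0.59 ± 0.10), Pate11 (10584252, 0.57 ± 0.15), Pou4f3 (10455335, 0.56 ± 0.14) and Edn3 (10479165, 0.55 ± 0.11). They were followed by Hmx3 (10558239, 0.54 ± 0.11), Prp2 (10542239, 0.53 ± 0.14), Tmem72 (10547191, 0.53 ± 0.11), Prr23a1 (10588073, 0.52 ± 0.12) and Gm7932 (10538159, 0.52 ± 0.11). Edn3 encodes an endothelin, and Pou4f3 and Hmx3 transcription factors of the inner ear. Adjusted p for these 20 genes lay between 0.033 and 0.0496. The rises were mostly dim: their median level was 6.71, against 8.28 for the falls and 8.41 for all genes tested, and 92.2% of them lay below that median of all genes. Dimmer genes had a median change of 0.11, and brighter genes of -0.04. Cytokine genes fell as a list (16 of 19 lower, median -0.23, camera adjusted p = 0.0357, adjusted p = 0.764 with an estimated correlation, adjusted p = 0.0579 after quantile normalization). Members with the smallest p were Cxcl5 (10523120, -0.42 ± 0.15), Il6 (10520452, -0.59 ± 0.21), Ccl2 (10379511, -0.26 ± 0.09) and Cxcl2 (10523156, -0.84 ± 0.33). The interferon response fell as a list (18 of 21 lower, median -0.12, camera adjusted p = 0.0357, adjusted p = 0.764 with an estimated correlation, adjusted p = 0.146 after quantile normalization). Its smallest p-values belonged to Gbp3 (10496580, -0.52 ± 0.17), B2m (10475414, -0.12 ± 0.04), Ifih1 (10483110, -0.38 ± 0.14) and Ifit2 (10462613, -0.40 ± 0.21). Endothelial markers, with a median level of 6.39, rose as a list (9 of 9 higher, median 0.17, camera adjusted p = 0.0357, adjusted p = 0.764 with an estimated correlation, adjusted p = 0.455 after quantile normalization). No member of these 3 lists passed when adjusted over the list alone. In other lists single members passed over all genes: Hspb1 rose (0.33 ± 0.09), as did the connexin gene Gja3 (10420359, 0.29 ± 0.08), while Atg3 (10435963, -0.43 ± 0.10), Itga1 (10412298, -0.36 ± 0.10), Pdia3 (-0.25 ± 0.07) and Fth1 (10461402, -0.11 ± 0.03) fell. They encode an autophagy enzyme, an integrin, a disulfide isomerase and the ferritin heavy chain.

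Arrays of the arms did not overlap in the incubator for 35.0% of genes, where chance gives 10% if all 6 arrays are exchangeable. Sets stood apart in groups on the first principal component, so that share is not exact here. The IgG incubator arrays were also the control for every platform position of that arm. An offset of those arrays would move both results, so they are not separate support. Dimmer and brighter genes changed by 0.11 and -0.04 here, and by 0.05 and -0.03 for the mean of the 3 positions against C in the IgG arm. The count of 423 depended on single arrays: it was 0 without IgG replicate 1, 0 without IgG replicate 2, 928 without IgG replicate 3, 15 without E2 replicate 2 and 0 without E2 replicate 3 of the incubator. It was 46 after quantile normalization (80.4% of them higher, against 54.8% as deposited), 60 with no filter on dim probe sets, 0 with the set as a random block and 0 when only the 6 incubator arrays were fitted.

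On the platform, the interferon response was lower in the E2 arm at 2g (19 of 21 lower, median -0.17, camera adjusted p = 2.07e-04, adjusted p = 0.937 with an estimated correlation). It was lower at ug as well (21 of 21 lower, median -0.21, camera adjusted p = 2.00e-04, adjusted p = 0.982 with an estimated correlation). At ug the members with the smallest p were Ifih1 (-0.50 ± 0.14), Ifit2 (-0.60 ± 0.21), Gbp3 (-0.47 ± 0.17) and Oasl1 (10524631, -0.32 ± 0.14), and Ifih1, a sensor of double-stranded RNA, passed when adjusted over the list alone. Cytokine genes fell at 2g (17 of 19 lower, median -0.18, camera adjusted p = 6.26e-04, adjusted p = 0.937 with an estimated correlation). Among them were Icam1 (10583519, -0.28 ± 0.10), Ccl2 (-0.19 ± 0.09), Cxcl5 (-0.28 ± 0.15) and Il6 (-0.37 ± 0.21). Also at 2g the unfolded protein response was lower (16 of 20 lower, median -0.06, camera adjusted p = 0.0334, adjusted p = 0.937 with an estimated correlation). Oxidative phosphorylation was higher there (18 of 23 higher, median 0.07, camera adjusted p = 2.07e-04, adjusted p = 0.937 with an estimated correlation). Adjusted over the list alone, Ndufa9 (0.23 ± 0.06) passed. At ug the immediate early genes were higher in the E2 arm (23 of 24 higher, median 0.39, camera adjusted p = 1.30e-08, adjusted p = 0.982 with an estimated correlation). They included Fosb (1.09 ± 0.36), Nr4a1 (10427035, 1.14 ± 0.40), Btg2 (10357875, 0.37 ± 0.13) and Klf2 (10572800, 0.33 ± 0.12). Without the 2g and ug arrays of set IgG 2 that list's adjusted p was 0.00124. At 1g no list passed. Limma called 0 genes at 1g, 0 at 2g and 0 at ug, with 1804, 626 and 1862 at an unadjusted p below 0.05. Without E2 replicate 3 at 1g, 14 genes were called there. Arrays of the arms did not overlap for 13.3% of genes at 1g, 9.42% at 2g and 17.0% at ug, against 10% by chance if the arrays are exchangeable.

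Whether the antibody's effect differed between platform and incubator was tested as a difference of differences. Each such difference includes the IgG incubator arrays, so an offset of those arrays would enter it as well. Ribosomal proteins rose in the E2 arm relative to the IgG arm at 1g (14 of 16 higher, median 0.07, camera adjusted p = 5.48e-05, adjusted p = 0.684 with an estimated correlation, adjusted p = 0.558 after quantile normalization). They did so at 2g (15 of 16 higher, median 0.06, camera adjusted p = 3.98e-04, adjusted p = 0.564 with an estimated correlation, adjusted p = 0.227 after quantile normalization). The same held at ug (15 of 16 higher, median 0.08, camera adjusted p = 1.24e-07, adjusted p = 0.262 with an estimated correlation). Targets of NRF2 rose by this measure at 1g (19 of 19 higher, median 0.09, camera adjusted p = 0.00122, adjusted p = 0.172 with an estimated correlation, adjusted p = 0.558 after quantile normalization). Members with the smallest p there were Gsta4 (10587315, 0.36 ± 0.21), Pgd (10518570, 0.13 ± 0.08), Sod2 (10441815, 0.14 ± 0.12) and Mt1 (10574027, 0.12 ± 0.14). At 2g the list rose too (16 of 19 higher, median 0.09, camera adjusted p = 0.024, adjusted p = 0.488 with an estimated correlation, adjusted p = 0.326 after quantile normalization). At ug it did likewise (18 of 19 higher, median 0.09, camera adjusted p = 0.00243, adjusted p = 0.262 with an estimated correlation, adjusted p = 0.267 after quantile normalization). With the block the difference in targets of NRF2 at 1g held with an estimated correlation (adjusted p = 0.0227). Oxidative phosphorylation rose by the same measure at 1g (15 of 23 higher, median 0.03, camera adjusted p = 0.0276, adjusted p = 0.7 with an estimated correlation, adjusted p = 0.986 after quantile normalization), where it turned downward after quantile normalization. It also rose at 2g (20 of 23 higher, median 0.06, camera adjusted p = 1.98e-05, adjusted p = 0.488 with an estimated correlation). Its rise passed at ug (20 of 23 higher, median 0.06, camera adjusted p = 2.57e-05, adjusted p = 0.461 with an estimated correlation, adjusted p = 0.123 after quantile normalization). Immediate early genes were higher at ug (23 of 24 higher, median 0.28, camera adjusted p = 2.05e-07, adjusted p = 0.461 with an estimated correlation). Cytokines were higher there (15 of 19 higher, median 0.12, camera adjusted p = 0.00468, adjusted p = 0.461 with an estimated correlation). Autophagy and lysosome genes were as well (15 of 19 higher, median 0.07, camera adjusted p = 0.0415, adjusted p = 0.602 with an estimated correlation, adjusted p = 0.505 after quantile normalization). Without the 2g and ug arrays of set IgG 2 the cytokine list had an adjusted p of 0.146. Endothelial markers were lower at 2g (9 of 9 lower, median -0.17, camera adjusted p = 0.0141, adjusted p = 0.488 with an estimated correlation, adjusted p = 0.227 after quantile normalization). Dimmer genes had a median difference of -0.08 at 1g, -0.08 at 2g and -0.07 at ug, and brighter genes of 0.03, 0.03 and 0.01. Ribosomal proteins, targets of NRF2 and oxidative phosphorylation were bright, with median levels of 12.2, 11.9 and 10.9, and endothelial markers were dim (6.39). The differences of these lists went the way of this shift by level.

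Limma called 0 genes for the difference at 1g, 0 at 2g and 0 at ug, with 681, 866 and 523 at an unadjusted p below 0.05. Without E2 replicate 1 at 1g, 1 gene was called there, and 2 with the set as a random block. With the block, camera called 8 lists at 1g instead of 3, adding cytokines, iron handling, cholesterol synthesis, extracellular matrix and autophagy genes, all higher (adjusted p between 0.00609 and 0.0229, and between 0.577 and 0.590 with an estimated correlation). For the mean of the 3 positions, a difference chosen after the data were seen, limma called 0 genes (1746 at an unadjusted p below 0.05). The targets of NRF2 rose in the E2 arm relative to the IgG arm by that measure (18 of 19 higher, median 0.08, camera adjusted p = 3.01e-06, adjusted p = 0.0362 with an estimated correlation). After quantile normalization the adjusted p of that list was 0.0446. Camera called 7 other lists: ribosomal proteins, oxidative phosphorylation, cytokines, autophagy, immediate early genes and iron handling were higher, and endothelial markers lower (adjusted p between 3.01e-06 and 0.0403, and between 0.163 and 0.734 with an estimated correlation). After quantile normalization none of these 7 was called (adjusted p between 0.103 and 0.422). By this measure dimmer genes had a median difference of -0.08 and brighter genes of 0.02.

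Changes at the positions were correlated across genes, which are not independent replicates. In the IgG arm r lay between 0.740 and 0.828, where simulated groups with no effect that share the incubator arrays gave 0.499, and the covariance exceeded the simulated 0.00437 by 0.00657 to 0.00933. In the E2 arm r lay between 0.382 and 0.483, and the covariance differed from the simulated one by -0.00055 to 0.000751. The incubator arrays were too few to split, so part of the excess in r may come from sharing them. Between the arms, which share no array, r was 0.194 at 1g, -0.0474 at 2g and 0.248 at ug. No position gave a gene called in both arms, since limma called 0 in each.

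Another 14 lists passed in none of the 15 comparisons of the design by camera without the block. Their lowest adjusted p (camera) was 0.0514 for iron handling, 0.0583 for hypoxia and glycolysis, 0.0617 for cholesterol synthesis, 0.065 for Wnt pathway, 0.0769 for muscle markers, 0.0994 for osteocyte markers, 0.121 for YAP and SRF targets and actin cytoskeleton. It was 0.121 for cell cycle, 0.161 for osteoblast markers, 0.236 for gap junction, pannexin, purinergic and prostaglandin genes, 0.265 for TGF-beta and BMP response, 0.317 for adipocyte markers, 0.344 for focal adhesion and integrins and 0.518 for macrophage and blood cell markers. The macrophage and blood cell, muscle and adipocyte markers, which stand for other cell types, had median levels of 6.5, 6.51 and 7.20.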

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

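The tests on the 2g and ug labels of set IgG 2, on harvest and on the arm labels and batches of the sets were chosen only after the result was seen, and so were the comparisons over both arms.

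Differences of the antibody's effect between a platform position and the incubator passed camera for 13 combinations of list and position, by the test of the difference itself. All positions were set against the same incubator arrays, so results for 1 list at several positions are not independent. Adjusted p was 0.00122, 0.024 and 0.00243 for targets of NRF2 at 1g, 2g and ug, 5.48e-05, 3.98e-04 and 1.24e-07 for ribosomal proteins, and 0.0276, 1.98e-05 and 2.57e-05 for oxidative phosphorylation. It was 0.0141 for endothelial markers at 2g, and at ug 0.00468 for cytokines, 2.05e-07 for immediate early genes and 0.0415 for autophagy genes. With an estimated correlation all 13 lay between 0.172 and 0.700 without a block. With the replicate block within arm, targets of NRF2 at 1g had 0.0227 and so passed.

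Among 6855 rows with no gene symbol or several, which no comparison of genes used, limma called 163 for E2 against IgG in the incubator, 55 for the same at 1g, 1 for 1g against C in the IgG arm and 1 for the difference of antibody effects at 1g.

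Other ways to split the arrays were counted for each result. E2 against IgG in the incubator called 423 genes, more than any other of its 10 splits (1 of 10 gave as many, highest other 0), but 10 splits are too few for a share under 0.05. The other 11 comparisons of 3 against 3 arrays called 0, so all 10 of 10 splits gave as many, with a highest other of 10 for ug against C in the E2 arm, 1 for 1g against C in the E2 arm, 1 for E2 against IgG at 1g and 0 for the rest. For the differences of antibody effects, all 100 of 100 splits gave as many, which a count of 0 fixes in advance. Of 99 drawn splits, 1 called genes at 1g (1244), 0 at 2g and 6 at ug (highest 2459); these few point to a structure of the samples other than the groups, which was not tested by them. Choosing another array of each set as the incubator array gave as many as the labels in 1 of 64 ways for the mean of the 3 positions in the IgG arm (102, highest other 17) and in 1 of 100 for both arms (97, highest other 5). Turning ug and C around within sets did so in 1 of 32 ways (91, highest other 6). That count does not allow for the choice of these 3 results after the data were seen, so it cannot exclude chance for them.

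Immediate early genes were higher on the ug than on the 2g array for 18 to 23 of 24 members in 5 sets, but for 2 in set IgG 2. Against their own incubator array, 15 of 24 were higher on the ug array of set IgG 1, 11 on that of IgG 2 and 18 to 24 on the other 4, and 22 on the 1g array of set E2 1. The 2g and ug labels of set IgG 2 may have been exchanged: across 14465 genes outside the list, its ug minus 2g difference had r = -0.304 with the mean of the other 5 sets, while each of those had r between 0.0502 and 0.391 with the mean of its own others. Genes are not independent replicates, and the exchange needs both arrays out of place. No label records a disturbance of the dishes at harvest, and one limited to the ug dishes cannot be told apart from the ug position, which stays open and untested; the list's median was 0.252 above 1g over both arms.

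Sets IgG 1, IgG 2 and E2 3 stood apart from sets IgG 3, E2 1 and E2 2 on the first principal component. The arm labels of the sets numbered 3 may have been exchanged, or the sets may come from separate batches: means over the 4 environments were separated completely for 4028 genes by the labelled arms and for 5368 by the arms with the sets numbered 3 exchanged, against 348 to 887 for the other 8 splits, and limma on those means called 0 genes (3129 at an unadjusted p below 0.05) and 3203 genes. The bound first written against an exchange, that the labelled split separates at least 1.5 times as many genes as the highest of those 8, was met by 4028 against 887. It was set aside after that result was seen, as wrong from the design: both splits keep the sets numbered 1 and 2 of each arm apart, so a gene that parts those 4 and scatters in the sets numbered 3 counts for either. The exchanged split was first seen on the principal component of these same arrays, so its counts are no separate support. Within single environments, exchanging the arrays numbered 3 gave 0 calls at C, 1g, 2g and ug, where the labels gave 423, 0, 0 and 0. Arrays of the other environments kept their labelled groups in those fits and enter the spread, so these counts do not decide. An exchange and a batch cannot be told apart with no label naming a day or batch, and an effect of the antibody, which the design gives, stays open.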

How the results depend on the processing

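The set as a random block, the fits without the 2g and ug arrays of set IgG 2 and all comparisons of the mean of the 3 positions or of both arms were tests chosen only after the result was seen. "Pseudocount 1" was not run, since the values are already log2.

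For E2 against IgG in the incubator the 423 genes became 46 after quantile normalization, 60 with no dim filter (19938 genes tested), 0 with the set as a random block, 0 with only the 6 incubator arrays and 0 to 928 leaving out a replicate (0 without IgG replicate 1, 0 without IgG replicate 2, 928 without IgG replicate 3, 15 without E2 replicate 2, 0 without E2 replicate 3). For 1g against C in the IgG arm the 0 became 7 with the replicate block within arm and 3 with the random block. The difference of antibody effects at 1g went from 0 to 2 with the random block and to 0 to 1 leaving out a replicate. Leaving out a replicate also gave 0 to 14 for E2 against IgG at 1g and 0 to 1 for ug against C in the E2 arm. Apart from fewer arrays or more genes tested, the cause was not tested.

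The 3 added comparisons with calls all fell to 0 with no replicate block. The mean of the 3 positions in the IgG arm (102) became 67 with no dim filter, 47 without a trend, 20 with the random block, 4 without the 2g and ug arrays of set IgG 2 and 0 to 2 leaving out a set. Over both arms (97) it became 43 after quantile normalization (19 higher and 24 lower, against 15 and 82), 59 with no dim filter, 35 without a trend, 8 with the random block, 13 without those arrays and 1 to 81 leaving out a set. Ug against C over both arms (91) became 20 without a trend, 22 with the random block and 0 to 110 leaving out a set; it was 94 without those arrays (62 higher and 32 lower, 61 of them among the 91) and 64 after quantile normalization (36 higher and 28 lower, against 35 and 56). Ug against 1g and against 2g over both arms (0 each) became 65 and 56 without those arrays and 0 to 47 and 0 to 48 leaving out a set. Ug against 1g became 1 with no dim filter and 1 with the random block. The cause was not tested.

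Oxidative phosphorylation in the difference at 1g turned from higher to lower after quantile normalization (adjusted p = 0.986); the cause was not tested. Over all 22 comparisons, quantile normalization ended 43 other list results and gave 9, and the estimated correlation ended 98. Fry on the blocked fit, also chosen after the data were seen, ended 83 list results and gave 3. In the design's comparisons it called the targets of NRF2 for 1g and 2g against C in the IgG arm and for the difference at 1g, ribosomal proteins for ug against C in the E2 arm and the difference at ug, and the TGF-beta and BMP response for 1g against C in the IgG arm. Of these, targets of NRF2 at 2g and in the difference at 1g and the TGF-beta and BMP response were gained when the scaling of genes for fry was changed after its first results had been seen. The block within arm gave 26 list results and ended 1. The number as a block over all arrays gave 4 list results and left every count of genes within 1.5 times (520 for E2 against IgG in the incubator, 393 of them among the 423). Of the genes named for that comparison, it ended the call of Alkbh8 and gave that of Gbp3. The block changed no other call of a list or gene count in the comparisons it could be fitted to. For the 4 comparisons that called genes, 13 of 49 counts under an alternative stayed within 1.5 times and 36 did not. For the 18 that called 0, 253 of 268 counts stayed at 0, which a floor allows. Dim probe sets limit the E2 comparison, since 92.2% of its rises lay below the median level of all genes.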

Other observations

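The comparisons over both arms and of the mean of the 3 positions, the quantile alternative of the latter, and the tests of temperature, of gravity and of the genes named in this part were chosen only after the result was seen; the bound of the normalization test was written before its own result.

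Gem (10503334), which encodes a small GTP-binding protein, was singled out after its values were seen: ug minus C was 1.89, -0.09, 3.74 (log2) in sets IgG 1, 2 and 3 and 2.25, 3.75, 2.73 in E2 1, 2 and 3, and ug minus 2g in set IgG 2 was -2.72. It rose at ug over both arms (2.38, limma adjusted p = 0.0272), in 5 of 6 sets, and set IgG 2 went the other way. Genes called in that comparison from lists described elsewhere only as lists included Hmox1 (0.34 ± 0.07, adjusted p = 0.0446), the enzyme that breaks down haem, Nfkbia (0.24 ± 0.05, adjusted p = 0.0282), an inhibitor of NF-kappaB, and Rpl13 (0.13 ± 0.03, adjusted p = 0.0446), which rose, and Vcam1 (-0.14 ± 0.03, adjusted p = 0.0345), Lox (-0.15 ± 0.03, adjusted p = 0.0249), Itga1 (-0.30 ± 0.07, adjusted p = 0.0495) and Adm (-0.22 ± 0.05, adjusted p = 0.047), the gene of adrenomedullin, which fell (limma with the block). Between ug and 2g over both arms, 17 of 24 immediate early genes were higher when adjusted over the list alone, and genes of hypoxia and glycolysis were lower as a list (17 of 20 lower, median -0.04, camera adjusted p = 0.00802, adjusted p = 0.481 with an estimated correlation). Cirbp, a gene raised by cold, fell in the IgG arm for the mean of the 3 positions. The differences by set were -0.32, -0.34, -0.31 in the IgG arm and -0.34, -0.08, -0.07 in the E2 arm (limma adjusted p = 0.0165 in the IgG arm, 0.622 in the E2 arm and 0.405 for the difference between arms).

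Platform and incubator differed in the IgG arm for 102 genes, the mean of 3 positions against C. A different scaling of the arrays was examined by quantile normalization, after which 81 genes were called, within the bound written for that test. Of these, 47 were among the 102, which argues against scaling as the whole cause for those 47. For the other 55 the calls ended, and rises went from 17 to 49 and falls from 85 to 32. Scaling may thus account for part of the falls. Over both arms the count of the same comparison, given above, fell further under quantile normalization. That fall would meet the bound for scaling as the cause, which was written for the IgG arm only. Warmer dishes on the platform are a candidate explanation: the heat shock list had a median of 0.0048, with members both ways, which decides nothing, while Hspa1a and Hspb1 rose. Altered gravity was examined through the 1g position, in the direction of the change. The 102 genes had a median of 0.28 for 1g minus C and of 2.53e-04 for the mean of 2g and ug minus 1g, where 0.28 would be needed. They were called with the 1g arrays included, which favours such values. For 60 genes chosen from 2g and ug alone, 1g minus C was 0.27 and the mean of 2g and ug minus C was 0.31. Their mean of 2g and ug minus 1g, which uses no incubator array, was 0.04 (0.04 to 0.06 by set). It argues against altered gravity as the whole cause for these 60 genes, unless another difference between positions offset it, and a small part stays open. All differences from C share the same incubator arrays, so an offset of those arrays would give such values too. No label gives the temperature of the platform, so warmth and the magnetic field cannot be told apart, and the latter stays untested.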
